A study of Arabidopsis thaliana with 24 samples.

How the data were processed

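Total RNA of sorted, protoplasted root meristem cells was sequenced in 24 libraries of 3 Arabidopsis reporter lines, with 3 zones per line. The PUB25 and SPT lines had 3 libraries per zone and the TMO5 line 2. RNA was extracted with the QIAGEN RNeasy micro kit and libraries were made with the NuGEN Ovation ultralow kit, per the labels. Bowtie, TopHat, Cufflinks and Cuffdiff on TAIR10 were used per the submitters' processing notes, which give no versions, roles or order. The deposited values are the authors' FPKM, 1 per gene, line and zone, and how the libraries of a zone were pooled is not stated. The authors' deposited table of each line also holds a log2 fold between zones and a q value (an adjusted p-value of the authors' test). For genes above 0 FPKM in both zones the deposited Distal over Proximal log2 folds were recomputed from the deposited FPKM and differed by at most 4.59e-05. The folds of the other zone pairs were not recomputed in this way. Where 1 zone is at 0 FPKM the authors' log2 fold is listed as 0. The smallest q value in the authors' deposited table was 0.000407 for the PUB25 line, 0.000359 for the SPT line and 0.00777 for the TMO5 line, so a common run of the 3 lines cannot be assumed and levels were not tested between lines. The files hold no counts, so the depth per library is unknown and no interval or detection limit is given.

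The files hold 32619 gene rows and 33474 loci. Rows that join several genes (1390) kept their joined name, so CYCB2;1, ARF19, AHK3, LHW, SACL3, CALS7, BRN1 and RCPG, which lie in such rows, were not measured as list members. For 606 names with several loci the authors' table carries 1 locus. Of the rows 27219 matched the TAIR10 reference and 9977 rows of a single gene had a symbol there. Positions are the deposited loci, counted from 1, and no position is given for a name with several loci. They can be wider than the annotated gene. Of 26605 single loci 17.9% had the exact start and end of the reference gene and 99.0% covered it within 1000 bases.

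The design chosen before the data were examined was a limma test on log2(FPKM + 1) per library. With 1 value per zone that test could not be run, and the design's stated fallback was used, with levels and fold changes as values. The authors' FPKM were transformed to log2(FPKM + 1), and genes with a mean of at least 1 FPKM over the 3 zones of a line were kept. A difference of at least 2-fold was counted with no test, and calls at a q value under 0.05 in the authors' deposited table are given beside it. Gene lists, the comparisons and the naming rule were also fixed before the data were examined. For each list of at least 5 measured members the median fold was ranked among 10000 random lists drawn from 20 bins of mean level. The central 95% runs from percentile 2.5 to 97.5. The deposited tables give q values and no unadjusted p-value, so a count adjusted over the list alone could not be computed, and the set test camera was not run.

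The naming rule took the reporter genes, PLT1, PLT2 and WOX5. It then took, by size with no threshold, the 6 largest rises and 6 largest falls between Distal and Proximal, 2 each way for the other zone pairs and 5 each way between lines, among genes with a symbol and at least 5 FPKM in the higher zone. Up to 4 members of each list, and any needed to describe it, were added. Many genes taken by size were short RNAs listed at 0 FPKM in 1 zone, for which no fold is given. A further selection, chosen after the values were seen, took the genes of the same ranks that were above 0 FPKM in both zones and had a q value under 0.05 in the authors' deposited table.

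The alternatives were a pseudocount of 0.1, no filter on low values, a minimum mean of 5 FPKM, quantile normalization and median centring of the zones. After the data were seen, leaving out joined rows and names with several loci, the authors' q value in place of a 2-fold difference, and for SPT minus PUB25 only genes passing the filter in both lines, were added. The computation was tested on simulated data in which 200 genes changed 4-fold, and 99.0% to 100% were recovered with at most 4 unchanged genes called. The noise there was independent and of a chosen size, so this checks the code and is no error rate for the real values, whose spread is unknown. Between 3 and 8 of 100 random lists lay outside the central 95% there. Tools were numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Lists for photosynthesis, with at most 1 measured member, and the lists of phloem, root cap and pericycle in lines with under 5 measured members have no percentile.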

Results

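RNA was measured by sequencing in protoplasts of Arabidopsis thaliana Col-0 root meristems, sorted by the intensity of a green fluorescent reporter into 3 populations named Proximal, Medial and Distal. The labels do not say which reporter intensity each population had or what the zone names are relative to, so the names are used here as labels only. The 24 libraries came from 3 reporter lines. The PUB25 and SPT lines sampled the root meristem, with 3 libraries per zone, and the TMO5 line sampled meristematic xylem, with 2 libraries per zone. The values are the authors' FPKM (fragments scaled by transcript length and by library size), with 1 value per gene, line and zone over the libraries of that zone. There are therefore no replicate values, and no error, n or replicate check can be given for any level or fold below. Depth per library is unknown from the files. Fold changes and list medians are log2 ratios of FPKM + 1 computed here, not the folds of the authors' deposited table. The words rose and fell are used of genes with a q value under 0.05 in the authors' deposited table, which holds the authors' own test between zones. A list's percentile is the rank of its median among 10000 random lists matched for level, and describes these values without testing them against replicates. Positions are on TAIR10. The names PLT1, BBM, AHP6, BFN1, BRN2, CASP4, CYCB1;1, EXPA17, VND5, EDA11, HB17, TEL1, EMB1025, MLO10 and HSL2 stand at 2 loci each in the files, and the values given are those of the 1 locus carried by the authors' gene table.

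The reporter genes and the PLETHORA genes were highest in Proximal cells of the SPT line, apart from TMO5, which was highest in Medial cells. SPT, a bHLH transcription factor gene (AT4G36930, chromosome 4, 17414127 to 17416294), stood at 35.7 FPKM in Proximal and 13.8 in Distal cells of the PUB25 line. In the SPT line it went from 26.5 to 1.35 FPKM, and in the TMO5 line from 23.8 to 21.3 FPKM. The ubiquitin ligase gene PUB25 (AT3G19380, chromosome 3, 6714392 to 6716099) went from 9.15 to 5.01 FPKM in the PUB25 line. TMO5, a bHLH gene of early xylem (AT3G25710, chromosome 3, 9369519 to 9371394), went from 481 through 354 to 240 FPKM in the TMO5 line. These were falls by the q value of the authors' deposited table, except for SPT in the TMO5 line. In the SPT line PUB25 stood at 10.6, 6.30 and 7.91 FPKM in Proximal, Medial and Distal cells. Neither difference from Proximal was called there, nor that of TMO5 between Proximal (9.41 FPKM) and Medial cells (12.6 FPKM) of that line. PLT1, a PLETHORA factor that maintains the stem cell niche, fell from 47.4 to 7.94 FPKM in the PUB25 line and from 60.9 to 1.41 FPKM in the SPT line. PLT2 fell by 1.68 and 2.95 on the log2 scale in the same lines. In the TMO5 line PLT1 stood at 126, 148 and 137 FPKM in Proximal, Medial and Distal cells, but PLT2 only at 4.91, 7.83 and 4.47 FPKM. WOX5, the quiescent centre homeobox gene, was low throughout, from 0.289 FPKM in PUB25 Proximal to 5.16 FPKM in SPT Distal. Its rise in the SPT line, from 0.772 FPKM, had a q value under 0.05 in the authors' deposited table.

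**Figure D1:**
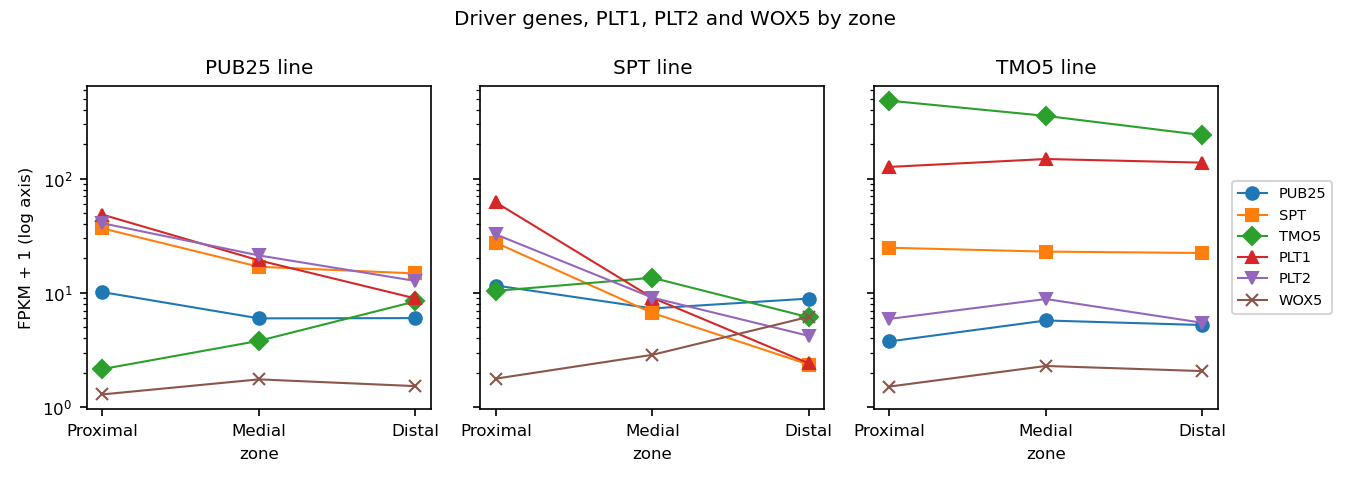
FPKM + 1 on a log axis of the 3 reporter genes, PLT1, PLT2 and WOX5 in the Proximal, Medial and Distal zones of each line, 1 point per zone and no error bars because there are no replicate values. PLT1 goes from 60.9 to 1.41 FPKM in the SPT line and stays between 126 and 148 FPKM in the TMO5 line.

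Distal against Proximal cells of the PUB25 line asked how these populations of the meristem differ. The root myrosinase genes BGLU35 (AT1G51470, chromosome 1, 19087382 to 19090539) and BGLU34 (AT1G47600, chromosome 1, 17491732 to 17494759) rose from 6.53 to 2338 FPKM and from 4.99 to 1829 FPKM, log2 folds of 8.28 and 8.26. MLP-300B, a myrosinase-binding protein gene, rose from 9.23 to 2202 FPKM, and the cis-prenyltransferase gene CPT from 0.872 to 371 FPKM. The ribonuclease gene RNS3 rose by 7.50 on the log2 scale and CSLB02, of the cellulose synthase superfamily, by 7.26. RGF2 (AT1G13620, chromosome 1, 4668443 to 4669471), which encodes a root meristem growth factor peptide, fell from 182 to 1.67 FPKM, and RGF3 from 132 to 2.73 FPKM. The actin depolymerizing factor gene ADF9 fell from 371 to 4.75 FPKM and the NAC factor gene NAC094 from 151 to 2.35 FPKM. FEZ, a NAC gene of root cap stem cells, fell by 4.96 and ENODL2, an early nodulin-like gene, by 4.51 on the log2 scale. Each of these 12 had a q value of 0.000407 in the authors' deposited table, the smallest it gives for this line. By size alone the list of falls also took in U60.2F, MIR168b and MIR390a, which are listed at 0 FPKM in Distal cells and at 96.6, 93.9 and 50.2 FPKM in Proximal cells. Of these only MIR390a passed, with a q value of 0.00731 in the authors' deposited table.

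The gene groups of the PUB25 line moved in several directions. Wall loosening and vacuolar water channel genes rose in 16 of 18 measured members and fell in 2 (the authors' deposited table), with a list median of 1.16 (percentile 100). The tonoplast channel gene TIP1;2 rose from 18.5 to 266 FPKM and XTH17 from 0.872 to 21.2 FPKM, while the expansin gene EXPA1 fell from 10.8 to 1.67 FPKM. Vessel wall and cell death genes rose in 14 of 16 members in the authors' deposited table (median 1.55, percentile 100). Among them MC9, a metacaspase gene, rose from 1.25 to 337 FPKM, the nuclease gene BFN1 from 0.339 to 104 FPKM and the laccase gene LAC4 from 4.16 to 17.9 FPKM. The highest level of MC9 in the xylem line TMO5 was 11.1 FPKM, so its rise here is not read as a xylem signal. Early vascular and xylem identity genes rose in 13 of 16 members in the authors' deposited table (median 1.39, percentile 100), such as ACL5 from 1.43 to 16.2 FPKM. AHP6, also among them, rose by 2.84 on the log2 scale. Ribosome biogenesis genes rose in 9 of 14 members and fell in 0 in the authors' deposited table (median 0.63, percentile 99.8), with FIB2 going from 157 to 343 FPKM and CBF5 from 189 to 366 FPKM. Growth-regulating factor genes rose in 4 of 7 members in the authors' deposited table (median 0.86, percentile 99.7), led by GRF1 from 6.07 to 23.8 FPKM.

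Genes of cell cycle exit rose in 6 of 11 members of the PUB25 line and fell in 2 in the authors' deposited table (median 0.87, percentile 99.9). The cyclin-dependent kinase inhibitor gene SIM rose from 1.14 to 18.6 FPKM and UPB1, a bHLH gene of the transition to elongation, from 6.89 to 43.2 FPKM. Mitosis genes fell in 10 of 24 members and rose in 0 in the authors' deposited table (median -0.30, percentile 1.20), KNOLLE from 80.5 to 48.7 FPKM. DNA replication genes had a median of -0.02 (percentile 54.4). Stem cell niche genes fell in 7 of 14 members in the authors' deposited table (median -0.45, percentile 0.60), and 2 rose, SHR from 2.58 to 21.5 FPKM and MGP from 2.02 to 4.46 FPKM. Wounding and heat response genes, which cell wall digestion can induce, fell in 10 of 15 members in the authors' deposited table (median -0.79, percentile 0), ZAT10 from 453 to 162 FPKM. Epidermis and root hair genes rose in 10 of 12 members in the authors' deposited table (median 1.04, percentile 100), GL2 from 4.72 to 20.8 FPKM. Root cap genes fell in 4 of 5 members in the authors' deposited table (median -1.34, percentile 0.070), SMB from 129 to 47.3 FPKM, while BRN2 rose from 45.3 to 229 FPKM. Endodermis and cortex genes had a median of 0.68 (percentile 98.7) with 3 of 8 members risen, CASP2 from 1.67 to 3.97 FPKM, in the authors' deposited table. Auxin genes rose in 13 and fell in 11 of 29 members in the authors' deposited table (median 0.02, percentile 34.0), IAA19 going from 29.9 to 236 and PIN4 from 227 to 32.5 FPKM. Brassinosteroid genes (median 0.10, percentile 68.5) and phloem genes (median 0.68, percentile 96.8) lay inside the central 95% of random lists, but phloem lay above it at 0.44 (percentile 99.9) with no filter on low values. The cytokinin median of 0.49 (percentile 99.9) did not hold its place, at 0.07 (percentile 87.1) with no filter on low values and 0.24 (percentile 90.2) with a minimum mean of 5 FPKM.

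In all, 1571 of 16605 measured genes stood at least 2-fold higher and 1159 at least 2-fold lower in Distal than in Proximal cells of the PUB25 line. The authors' deposited table calls 3353 risen and 2914 fallen. Of the 17 lists tested in this line, 9 lay above and 4 below the central 95% of random lists, where 0.85 would be outside for lists of unrelated genes. Genes of a list can vary together, so these counts are no test of an excess. Only 1811 genes differed 2-fold with a minimum mean of 5 FPKM, against 2730 in both directions at the minimum of 1 FPKM.

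The steps through Medial cells of the PUB25 line divided these changes. From Proximal to Medial, BGLU34 and BGLU35 rose by 6.36 and 6.24 on the log2 scale, while the arabinogalactan protein gene AGP5 fell by 2.58 and FEZ by 2.35. From Medial to Distal, the RNA editing factor gene OTP86 rose from 0.649 to 29.6 FPKM and MC9 from 54.1 to 337 FPKM, and ADF9 and RGF2 fell by 4.04 and 3.85 on the log2 scale. Each of these had a q value of 0.000407 in the authors' deposited table. By size alone the short RNAs SNOR95 and MIR172e, listed at 0 FPKM in Medial cells, MIR158b, listed at 0 in Proximal and Medial cells, and U60.2F and MIR168b, listed at 0 in Distal cells, came first. From Proximal to Medial 1194 genes stood at least 2-fold higher and 477 lower, and from Medial to Distal 539 and 508 (743 and 782 with a pseudocount of 0.1, and 289 and 387 with a minimum mean of 5 FPKM). The authors' deposited table calls 2462 risen and 1986 fallen in the first step and 1893 risen and 1904 fallen in the second.

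Distal against Proximal cells of the SPT line posed the same question in another whole-meristem reporter. BGLU35 rose from 1.05 to 1325 FPKM, MLP-300B from 1.94 to 1733 FPKM and BGLU34 from 2.08 to 1774 FPKM, log2 folds of 9.34, 9.20 and 9.17. The carboxypeptidase gene SCPL34 (AT5G23210, chromosome 5, 7810683 to 7815039) rose from 3.34 to 1250 FPKM, the homocysteine methyltransferase gene HMT3 from 1.22 to 417 FPKM and MC9 from 0.613 to 249 FPKM. ADF9 fell from 278 to 4.47 FPKM, RGF2 from 87.4 to 1.11 FPKM and RGF3 from 124 to 2.96 FPKM. PLT1, the calmodulin-binding IQD16 and FEZ fell by 4.68, 4.25 and 4.24 on the log2 scale. The q values of these 12 in the authors' deposited table were 0.000359, its smallest for this line, except 0.00122 for MC9 and 0.00454 for RGF2. By size the first rises also held CPT, at 0.127 and 233 FPKM, whose q value in the authors' deposited table was 0.371, and EDA11, listed at 0 FPKM in Proximal and 215 FPKM in Distal cells. The first falls also held U60.2F, U60.1F, MIR781a and MIR390a, all listed at 0 FPKM in Distal cells. MIR390a alone of these passed, with a q value of 0.0465 in the authors' deposited table.

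Ribosome biogenesis, DNA replication and mitosis genes fell together in the SPT line. In the authors' deposited table all 14 ribosome biogenesis genes fell (median -2.87, percentile 0), the nucleolin gene NUC1 from 322 to 34.2 FPKM and CBF5 from 425 to 28.1 FPKM. All 22 measured DNA replication genes fell in the authors' deposited table (median -2.14, percentile 0), PCNA1 from 140 to 16.8 FPKM and MCM3 from 37.2 to 5.21 FPKM. Mitosis genes fell in 23 of 24 members in the authors' deposited table (median -1.90, percentile 0), CYCB1;4 from 19.2 to 2.34 FPKM and KNOLLE from 60.1 to 9.09 FPKM. Stem cell niche genes fell in 11 of 15 members in the authors' deposited table (median -1.61, percentile 0), PLT3 from 134 to 43.8 FPKM. Growth-regulating factor genes fell in 3 of 7 members in the authors' deposited table (median -0.36, percentile 23.6), including the coactivator gene GIF1. The level of GIF1 fell by 3.32 on the log2 scale.

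Other lists of the SPT line differed in direction. Wall loosening and water channel genes rose in 16 of 20 members and fell in 3 in the authors' deposited table (median 2.47, percentile 100), TIP1;1 from 113 to 1100 FPKM. Vessel wall and cell death genes rose in 15 of 20 members in the authors' deposited table (median 3.09, percentile 100), the xylem peptidase gene XCP2 from 2.78 to 368 FPKM and the cellulose synthase gene CESA4 from 0.640 to 18.1 FPKM. Endodermis and cortex genes rose in 5 and fell in 2 of 11 members in the authors' deposited table (median 4.47, percentile 100). The Casparian strip genes CASP1 and CASP5 rose from 1.33 to 173 FPKM and from 0.425 to 42.3 FPKM, and the ground tissue gene SCZ fell from 22.0 to 1.14 FPKM. Genes of cell cycle exit rose in 6 of 11 members in the authors' deposited table (median 1.49, percentile 99.7), SIM from 4.88 to 41.3 FPKM. Auxin genes rose in 17 and fell in 6 of 31 members in the authors' deposited table (median 1.04, percentile 99.7), TAR2 going from 1.14 to 25.8 FPKM and PIN4 from 194 to 15.3 FPKM. Cytokinin genes rose in 12 and fell in 3 of 19 members in the authors' deposited table (median 0.96, percentile 99.5), ARR5 from 10.3 to 47.2 FPKM. Phloem genes rose in 8 of 13 members in the authors' deposited table (median 0.98, percentile 98.6), APL from 0.667 to 19.1 FPKM, and pericycle genes in 3 of 7 (median 1.46, percentile 98.7), PHO1 from 1.41 to 23.3 FPKM. The early vascular list rose in 2 and fell in 7 of 16 members in the authors' deposited table (median -0.36, percentile 29.8). Epidermis genes rose in 4 and fell in 3 of 11 members (median 0.03, percentile 59.6), and wounding and heat genes rose in 6 of 15 (median 0.54, percentile 56.4), in the authors' deposited table. Brassinosteroid genes had a median of -0.04 (percentile 39.0). Root cap genes, with 4 measured, were too few for a list value, and of these BRN2 rose from 5.33 to 233 FPKM and FEZ fell in the authors' deposited table.

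In the SPT line 4227 of 17365 measured genes stood at least 2-fold higher and 3791 at least 2-fold lower in Distal than in Proximal cells, which became 3625 and 4047 after quantile normalization. The authors' deposited table calls 4321 risen and 4038 fallen. Of its 17 lists 8 lay above and 4 below the central 95% of random lists.

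The steps through Medial cells of the SPT line had different leading genes. From Proximal to Medial, XCP2 rose from 2.78 to 648 FPKM and LAC4 from 0.336 to 67.6 FPKM in the authors' deposited table. TED6, of tracheary element differentiation, is listed at 0 FPKM in Proximal and 72.9 FPKM in Medial cells, and passed with a q value of 0.000359 in the authors' deposited table. RGF2 and RGF3 fell by 4.73 and 4.23 on the log2 scale in this step. From Medial to Distal, BGLU34 and BGLU35 rose by 7.65 and 7.43 on the log2 scale, while PMAT2, a malonyltransferase gene, fell by 2.77 and FEZ by 2.34. The q values in the authors' deposited table were 0.000359 for these genes and for RGF2 and RGF3 in the first step, except 0.000668 for FEZ. By size alone the falls began with U60.1F and MIR781a in the first step and U60.2F and MIR390a in the second, each listed at 0 FPKM in the later zone. At least 2-fold, 3030 genes stood higher and 2146 lower in Medial than in Proximal cells (2679 and 2757 after quantile normalization), and 1500 higher and 1244 lower in Distal than in Medial cells (1789 and 2225 with a pseudocount of 0.1). The authors' deposited table calls 3025 risen and 3035 fallen in the first step and 2067 risen and 1798 fallen in the second.

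**Figure D2:**
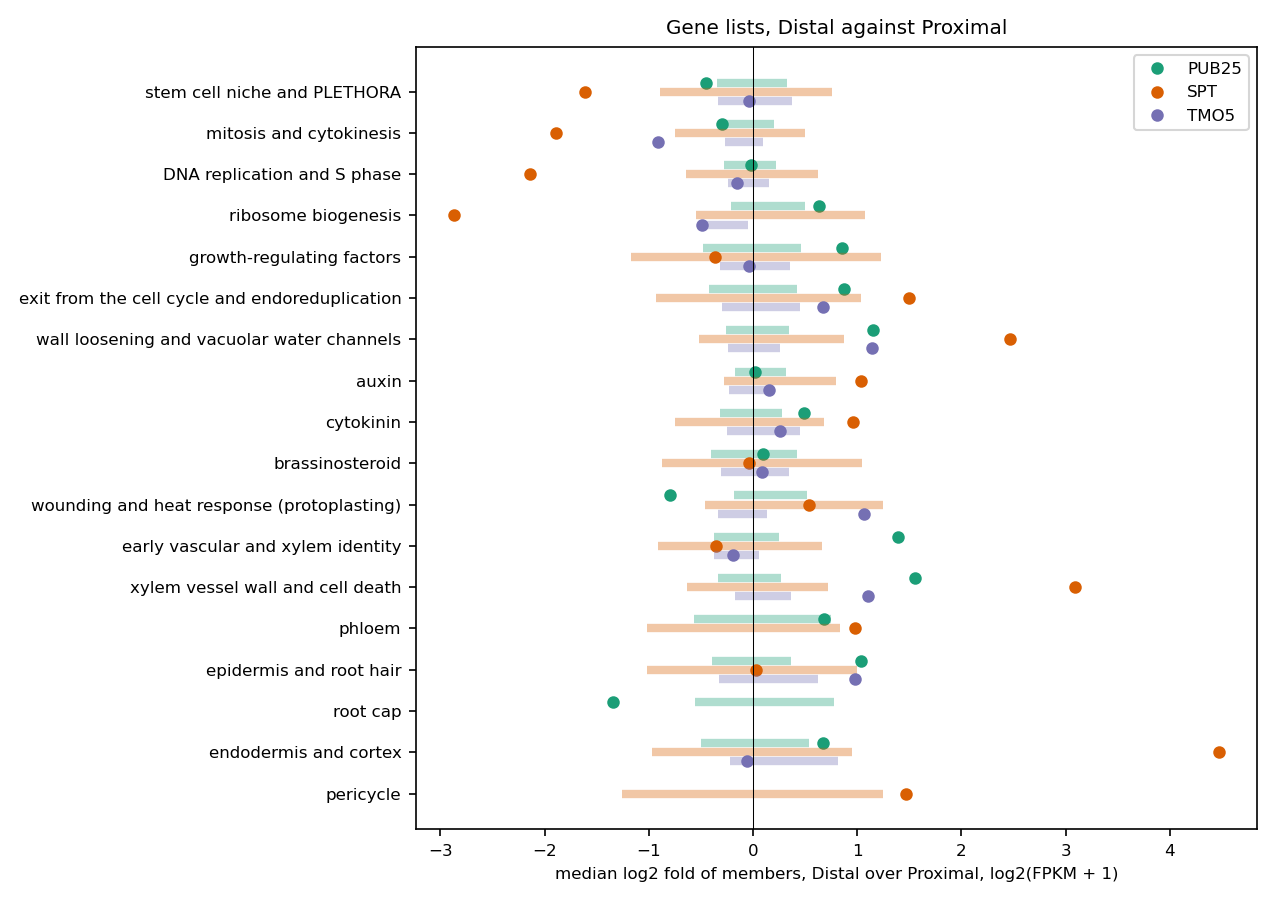
Median log2 fold of each gene list, Distal over Proximal, on FPKM + 1, 1 marker per line, for lists of at least 5 measured members. Ribosome biogenesis lies at 0.63 in the PUB25 line, -2.87 in the SPT line and -0.49 in the TMO5 line, and wall loosening at 1.16, 2.47 and 1.15.

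Distal against Proximal cells of the TMO5 line compared zones within meristematic xylem. BGLU35 rose from 5.73 to 75.4 FPKM, BGLU34 from 4.55 to 60.4 FPKM and MLP-300B from 4.70 to 30.1 FPKM, log2 folds of 3.50, 3.47 and 2.45. In SPT Distal cells these genes stood at 1325, 1774 and 1733 FPKM. A rise within xylem can therefore not be told apart from a few cells of other types in the TMO5 Distal sort. The proline-rich wall protein gene PRP1, MC9 and the trihelix factor gene GTL1 rose by 2.42, 2.21 and 2.14 on the log2 scale. AHP6, an inhibitor of cytokinin signalling in protoxylem (HP6 in the reference, AT1G80100), fell from 293 to 100.1 FPKM, and ENODL14 from 276 to 109 FPKM. The mitotic genes CYCB2;2 and BUBR1 fell from 19.8 to 7.33 FPKM and from 29.5 to 11.6 FPKM. NAKR2, a chaperone gene, and WES1, an auxin conjugation gene, both fell by 1.28 on the log2 scale. The q values of these 12 in the authors' deposited table ran from 0.00777 to 0.0497. By size alone the list was led by short RNAs. U60.2F, MIR830, SNOR77, MIR852, MIR164b and SNOR37-2 are listed at 0 FPKM in Proximal cells, MIR870, MIR158a, MLO10 and CASP4 at 0 FPKM in Distal cells, and OTP86 and HSL2 stood at 124 and 7.50 FPKM in Proximal and 16.1 and 0.867 FPKM in Distal cells. None of these 12 had a q value under 0.05 in the authors' deposited table.

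Division genes were lower and vessel and wall genes higher in Distal cells of the TMO5 line. Mitosis genes fell in 8 of 24 members and rose in 0 in the authors' deposited table (median -0.91, percentile 0), KNOLLE from 114 to 46.8 FPKM and CDKB2;1 from 143 to 70.0 FPKM. Ribosome biogenesis genes had a median of -0.49 (percentile 0.98), but 0 of 14 passed in the authors' deposited table. Vessel wall and cell death genes rose in 4 of 18 members and fell in 0 in the authors' deposited table (median 1.11, percentile 100), XCP2 from 167 to 405 FPKM and LAC4 from 9.03 to 25.1 FPKM. Wall loosening genes rose in 3 of 17 members in the authors' deposited table (median 1.15, percentile 100), TIP1;1 from 30.1 to 74.4 FPKM. Wounding and heat response genes rose in 3 of 14 members in the authors' deposited table (median 1.07, percentile 100), JAZ1 from 143 to 302 FPKM. The lists of cell cycle exit (median 0.67, percentile 99.5) and epidermis (median 0.98, percentile 99.8) lay above the central 95% of random lists, with 0 members called in the authors' deposited table. The epidermis value was 0.30 (percentile 84.4) with no filter on low values. Early vascular genes had a median of -0.19 (percentile 48.1), with TMO5 and AHP6 called fallen in the authors' deposited table. Stem cell niche (median -0.04, percentile 48.7), DNA replication (median -0.15, percentile 18.6), growth-regulating factor (median -0.04, percentile 47.6), auxin (median 0.15, percentile 96.7), cytokinin (median 0.26, percentile 88.2), brassinosteroid (median 0.08, percentile 76.2) and endodermis genes (median -0.06, percentile 12.2) lay inside the central 95%, except that endodermis lay below it at -0.09 (percentile 1.68) with no filter on low values.

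In the TMO5 line 1180 of 15061 measured genes stood at least 2-fold higher and 180 at least 2-fold lower in Distal than in Proximal cells, so 86.8% of them were higher. The share was 75.8% after quantile normalization and 79.4% after median centring, which moved the median of all genes by about -0.10. The authors' deposited table calls 193 risen and 41 fallen, and leaves 1141 of the genes with a 2-fold difference uncalled. Of its 15 lists 5 lay above and 2 below the central 95% of random lists, where 0.75 would be outside for lists of unrelated genes, again no test of an excess.

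Vessel genes were lowest in Medial cells of the TMO5 line, and the listed wounding and heat response genes moved with them. XCP2 stood at 167, 7.54 and 405 FPKM in Proximal, Medial and Distal cells, and both its fall in the first step and its rise in the second had a q value of 0.00777 in the authors' deposited table. MYB46, a master regulator of secondary walls, rose from 1.12 in Medial to 33.8 FPKM in Distal cells, with a q value of 0.0332 in the authors' deposited table. The vessel wall list had a median of -1.93 from Proximal to Medial (percentile 0) and 3.12 from Medial to Distal (percentile 100). The wounding and heat list had medians of -0.41 (percentile 0, 0 of 14 above 0) and 1.46 (percentile 100, 14 of 14 above 0) in the same steps. OTP86 fell from 124 to 1.08 FPKM in the first step, and the tubulin gene TUB5 and the desaturase gene ADS2 rose by 1.25 and 1.17 on the log2 scale. Their q values in the authors' deposited table were 0.00777, 0.0133 and 0.0218. By size the extremes of the 2 steps also held U60.2F, U60.1F, MIR781a and MIR870, each listed at 0 FPKM in at least 1 zone. At least 2-fold, 88 genes stood higher and 383 lower in Medial than in Proximal cells, and 1548 higher and 71 lower in Distal than in Medial cells. The authors' deposited table calls 4 risen and 28 fallen in the first step and 326 risen and 1 fallen in the second.

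**Figure D3:**
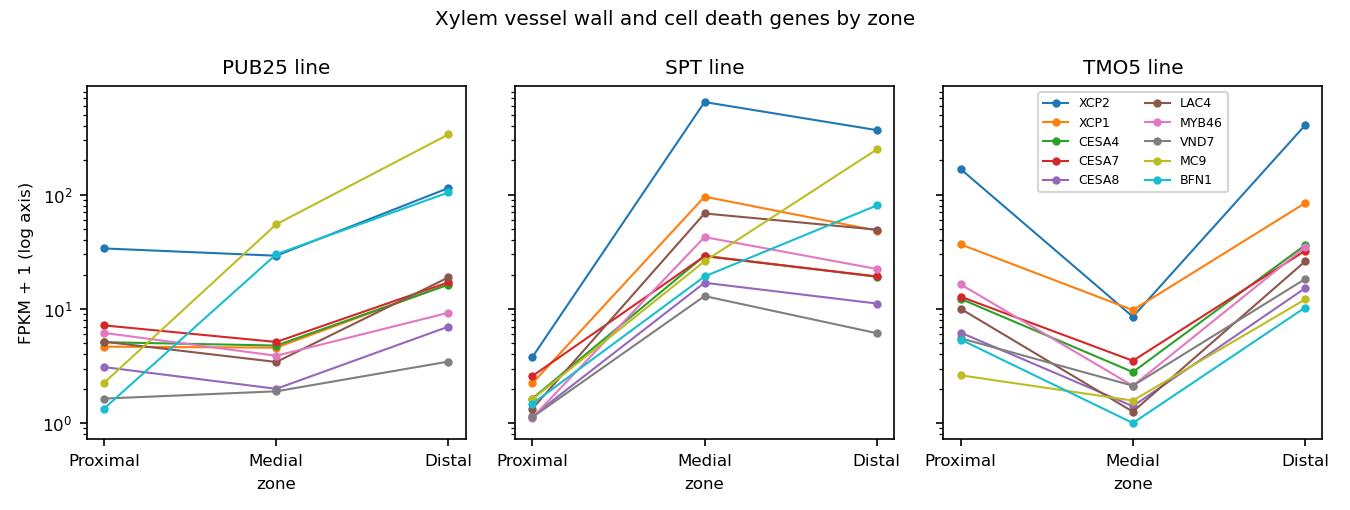
FPKM + 1 on a log axis of vessel wall and cell death genes in the 3 zones of each line, 1 point per zone and no error bars because there are no replicate values. XCP2 goes from 167 to 7.54 to 405 FPKM in the TMO5 line and from 2.78 to 648 to 368 FPKM in the SPT line.

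The zone differences of the 2 whole-meristem lines were set against each other to see how far they match. Ribosome biogenesis genes moved apart, with a median SPT minus PUB25 difference of -3.46 (percentile 0) and a lower value in the SPT line for 14 of 14 genes. DNA replication (median -1.99), early vascular (median -1.56), mitosis (median -1.49), stem cell niche (median -1.33) and growth-regulating factor genes (median -1.33) also had lower folds in the SPT line, and all 5 lay below the central 95% of random lists. Endodermis and cortex (median 3.85), vessel wall (median 1.68), auxin (median 1.29), wounding and heat (median 1.21) and wall loosening genes (median 1.18) had higher folds in the SPT line, above the central 95%, although wounding and heat came inside it (percentile 95.8) with a minimum mean of 5 FPKM. Only 1 pericycle gene and 4 root cap genes passed the filter in both lines, so no difference is given for these lists. Single genes called in opposite directions in the authors' deposited table included CKX4, a cytokinin oxidase gene, at 16.2 and 3.34 FPKM in Proximal and Distal cells of the PUB25 line and 0.863 and 16.6 FPKM in the SPT line. OTP86 and the mitochondrial translocase gene TOM7-2 were called the other way round in the authors' deposited table, TOM7-2 going from 9.18 to 49.6 FPKM in the PUB25 line and from 101 to 6.07 FPKM in the SPT line. By size MIR168b, MIR778, CASP4, U60.1F, PDF2.5 and MIR781a also led, none of them called in both lines in the authors' deposited table.

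Across 15908 genes, which are not independent replicates, the Distal over Proximal folds of the PUB25 and SPT lines had a Pearson r of 0.469 and a Spearman rho of 0.306, and 60.3% had the same sign. This was 1 of 3 such comparisons. The SPT and TMO5 lines had an r of 0.537 and a rho of 0.648, and the PUB25 and TMO5 lines an r of 0.164 and a rho of 0.049. In the authors' deposited table, 1793 genes rose in both the PUB25 and SPT lines, where independent lists of that size give 762, and 904 fell in both, where they give 689. Another 638 rose in the PUB25 line and fell in the SPT line, where independent lists give 779, and 394 fell in the PUB25 line and rose in the SPT line, where they give 674. The fold differed at least 2-fold between these lines in 7187 of 17387 genes, higher in the SPT line for 3768 and lower for 3419 (3485 and 3543 after quantile normalization, and 3208 and 3241 among genes passing the filter in both lines). These differences were not tested, since there is 1 value per zone.

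**Figure D4:**
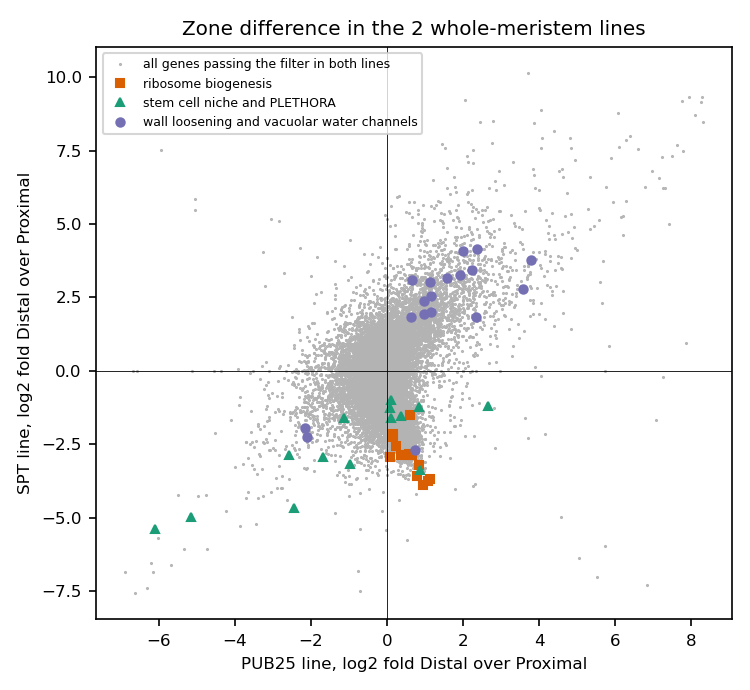
Log2 fold, Distal over Proximal, of each gene in the PUB25 line (x axis) and the SPT line (y axis), with 3 gene lists marked. Ribosome biogenesis genes lie at positive values for PUB25 and negative values for SPT, at medians of 0.63 and -2.87.

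The zone difference in xylem cells was set against the mean of the 2 whole-meristem lines. RGF2, ADF9 and RGF3, which fell in both whole-meristem lines in the authors' deposited table, stood at or below 1.65 FPKM in every TMO5 zone, so their difference was 5.97, 5.81 and 5.48 on the log2 scale. CPT, SCPL34 and MLP-300B had lower folds in the TMO5 line by -6.94, -6.25 and -6.03. SCPL34 went from 41.4 to 897 FPKM in the PUB25 line and from 4.40 to 4.55 FPKM in the TMO5 line. By size U60.2F, MIR390a, MIR870 and MLO10 also led, each listed at 0 FPKM in at least 1 zone. The fold was at least 2-fold higher in the TMO5 line for 1555 and lower for 1667 of 17156 genes, with no test, and for 2559 and 1973 with a pseudocount of 0.1. With a minimum mean of 5 FPKM 2119 genes differed, against 3222.

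Mean levels of the TMO5 line were set beside those of the whole-meristem lines, with no test, because the authors' smallest q values differ between lines and a common scaling of the lines is not stated. TMO5 (BHLH32 in the reference and the files) and AHP6 were higher in the xylem line by 5.79 and 5.11 on the log2 scale, followed by the homeobox gene HB17 at 5.03, the RNA-binding TEL1 at 4.82 and EMB1025 at 4.66. The SKU5-similar genes sks15 and sks16 stood at -6.90 and -5.87, the lipase-like GLL22 at -5.95, the peptidase gene AIR3 at -5.84 and the root cap gene SMB at -5.83. Early vascular genes were higher in 16 of 16 members (median 3.47, percentile 100), ribosome biogenesis genes in 14 of 14 (median 1.72, percentile 100) and mitosis genes in 24 of 24 (median 1.44, percentile 100). TMO5, on whose reporter the line was sorted, is among the early vascular genes, so its own excess is no independent result. Vessel wall and cell death genes were not higher as a list, with 9 of 19 members above 0 (median -0.16, percentile 58). Root cap (median -3.56, percentile 0.010), wounding and heat (median -2.38, percentile 0.020) and cytokinin genes (median -1.83, percentile 0, and -0.55, percentile 0.970, with no filter on low values) had lower medians in the TMO5 line, although 1 of 5, 3 of 15 and 6 of 18 members were higher there. At least 2-fold, 2094 genes stood higher and 4828 lower, a share of 30.3% higher. That share was 52.3% after quantile normalization and 51.6% after median centring, where the median of all genes went from -0.20 to 0.19 and 0.17.

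Medial levels were compared with those of the other zones for genes called between Distal and Proximal in the authors' deposited table that passed the filter. Medial lay between the others for 75.1% of 6113 genes in the PUB25 line and 85.8% of 8296 genes in the SPT line, at a median position of 0.58 and 0.60 of the way from Proximal to Distal. In the TMO5 line it lay between for 56.0% of 232 genes, at a median position of 0.068. Of the genes higher in Distal cells of the TMO5 line, such as XCP2 and LAC4, 46.9% of 192 had a Medial value between the others, and of those lower in Distal cells, such as AHP6 and KNOLLE, 100% of 40.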

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

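The tests of explanations in this part were chosen only after the results were seen. Ribosome biogenesis genes stood out because their zone difference had opposite signs in different lines. From Proximal to Distal 14 of 14 were above 0 in the PUB25 line (median log2 fold 0.63) and 0 of 14 in the SPT line (median -2.87), a difference of medians of -3.50. In the TMO5 line 0 of 14 were above 0 (median -0.49), a difference from the PUB25 line of -1.12. Neither difference was tested, since there is 1 value per zone. In the authors' deposited table, 1035 genes were called in opposite directions between Distal and Proximal of the PUB25 and SPT lines, also an untested difference. Opposite calls were fewer than independent lists give, at 638 against 779 and 394 against 674 among the 15908 genes that passed the filter in both lines.

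For the opposite movement of NUC1, FIB2, CBF5 and the other ribosome biogenesis genes in the PUB25 and SPT lines, the authors' scaling of the zones is argued against, since the median gene-by-gene difference was -3.46 as deposited and -3.54 after quantile normalization. A larger share of vascular cells in the PUB25 Distal sort may contribute to the rise in that line, but its size was not estimated. A larger share in that sort would not bear on the fall in the SPT line (median -2.87). Whether the share of such cells also differed between the SPT zones was not tested. The 63 genes at least 8-fold higher in the TMO5 line and outside the lists had a median Distal over Proximal fold of 0.68 in the PUB25 line (percentile 100, 48 above 0) and -0.92 in the SPT line (percentile 0, 27 above 0). Ribosome biogenesis genes were themselves higher in the TMO5 line by 1.72 against the mean of the whole-meristem lines. The gap to the PUB25 line alone was smaller, with mean log2 levels of 5.91 in Proximal and 6.51 in Distal cells there, against 7.40 and 6.90 in the TMO5 line. The 2 most abundant xylem identity genes of the TMO5 line, TMO5 and AHP6, stood at 1.15 and 1.23 FPKM in Proximal and 7.41 and 14.98 FPKM in Distal cells of the PUB25 line. In the TMO5 line they stood at 481 and 293 FPKM in Proximal and at 240 and 100.1 FPKM in Distal cells. Both genes were thus lower in the PUB25 line, but a common scaling of the lines is not stated. No share of such xylem cells is therefore read from these levels, and 2 xylem genes do not bound other vascular cells. The 16 measured early vascular genes passed the 1 FPKM filter in the PUB25 line by definition, so their presence there adds no support. Their median there was 1.465 FPKM in Proximal and 6.65 FPKM in Distal cells. The sort on the PUB25 reporter has no stated step that would remove vascular cells. Yet only 6 of 16 listed phloem and 1 of 7 pericycle genes passed the 1 FPKM filter in that line, against 13 and 7 in the SPT line. The early vascular list had 16 measured genes in each of these lines. A biological difference between the populations the 2 reporters mark stays open and was not tested.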

How the results depend on the processing

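Alternatives chosen only after the data were seen were the one without joined rows and names with several loci, the one counting the authors' q value in place of a 2-fold difference, and, for SPT minus PUB25, the one with only genes passing the filter in both lines. Between Distal and Proximal cells, no named or listed gene called in the authors' deposited table, and no list outside the central 95% of random lists, changed sign under any of the alternatives run. Of 112 alternative values of 17 counts, correlations and shares, 97 stayed close (counts within 1.5 times, correlations within 0.1, shares within 5 points) and 15 moved further. Of 285 values of 49 list medians 275 stayed within 1.5-fold and 10 moved, and of 4995 values of 880 gene folds 4834 stayed and 161 moved, all between Distal and Proximal cells. The lists and genes of the steps through Medial cells and of the differences between lines were rerun under the same settings only after the values were seen. Of 794 values of their 134 list medians 766 stayed, 24 moved and 4 changed sign, all 4 from Medial to Distal in the TMO5 line. The auxin median there, 0.11 (percentile 97.51), went to -0.0424 with a minimum mean of 5 FPKM, -0.0511 after quantile normalization and -0.0158 after median centring, and the cytokinin median, 0.51 (percentile 98.6), to -0.20 with a minimum mean of 5 FPKM (percentile 27.4). The SPT minus PUB25 difference of wounding and heat genes came inside the central 95% with a minimum mean of 5 FPKM (percentile 95.8). With only genes passing the filter in both lines, the lists outside the central 95% kept their sides, except that pericycle (1 gene) and root cap (4 genes) had too few members for a value. The cytokinin median of the TMO5 line against the whole meristem went from -1.83 to -0.55 (percentile 0.970) with no filter on low values. Of 15484 values of 2724 gene differences 15050 stayed, 434 moved and 0 called or named ones changed sign. With a minimum mean of 5 FPKM, the number of genes with a 2-fold difference in the PUB25 line was 1811 for Distal against Proximal (2730 as reported) and 676 for Distal against Medial (1047). In the TMO5 line it was 749 for Distal against Proximal (1360), 255 for Medial against Proximal (471), 797 for Distal against Medial (1619), and 2119 for the difference from the whole meristem (3222). Fewer genes enter at that minimum by construction. A pseudocount of 0.1 gave 2045 and 873 genes in the TMO5 line for Distal and Medial against Proximal, since it enlarges folds of low values. Counting the authors' q value under 0.05, in the authors' deposited table, gave 6267, 4448 and 3797 genes in the PUB25 line for Distal against Proximal (2730), Medial against Proximal (1671) and Distal against Medial (1047), and 234, 32 and 327 genes in the TMO5 line, since it replaces a size limit by a test. The share of genes with Medial between the other zones in the SPT line was 79.2% after quantile normalization (85.8%), and the cause was not tested. The larger side of the 2-fold counts changed under some settings. After quantile normalization SPT Distal against Proximal went to 3625 higher and 4047 lower, SPT Medial against Proximal to 2679 and 2757, and the SPT minus PUB25 difference to 3485 and 3543 (3208 and 3241 among genes passing the filter in both lines). With a pseudocount of 0.1 PUB25 Distal against Medial went to 743 and 782, SPT Distal against Medial to 1789 and 2225, and the TMO5 minus whole meristem difference to 2559 and 1973. With a minimum mean of 5 FPKM PUB25 Distal against Medial went to 289 and 387. For levels in the TMO5 line against the whole meristem, 2094 higher and 4828 lower went to 3672 and 3345 after quantile normalization and to 3654 and 3431 after median centring. Scaling moved the median of all genes by over 0.1 in some comparisons, to -0.15 (quantile) and -0.16 (centring) in Distal against Medial of the TMO5 line and to -0.12 (quantile) in Medial against Proximal of the SPT line. The sign of that median turned in Distal against Proximal of the SPT line, from 0.06 to -0.05 (quantile). It also turned in the TMO5 minus whole meristem difference, from 0.10 to -0.03 (centring).

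No paired analysis was possible because the files hold 1 value per zone, so a replicate block was not run. Leaving out each replicate, eBayes without trend, 1 fit over all 24 libraries and camera with an estimated correlation were not run for the same reason. Depth is unknown, so what it limits cannot be given as a number.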

Other observations

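Gene families read from the deposited titles, and the tests of explanations in this part, were chosen only after the values were seen. Ribosomal protein genes had medians of the same signs as the ribosome biogenesis genes. In the authors' deposited table, 154 of 244 rose and 3 fell in the PUB25 line (median log2 fold 0.51, Distal over Proximal), 6 rose and 212 fell in the SPT line (median -2.13), and 0 of 241 passed in the TMO5 line (median -0.50). Aquaporin genes rose in 18 of 21 members in the PUB25 line (median 2.17), 15 of 21 in the SPT line (median 2.42) and 5 of 18 in the TMO5 line (median 0.97) in the authors' deposited table. Pectin methylesterase genes rose in 17 of 27 and fell in 4 in the PUB25 line (median 1.11), rose in 16 of 31 and fell in 2 in the SPT line (median 1.88), and rose in 2 of 18 in the TMO5 line (median 0.73) in the authors' deposited table. Peroxidase genes rose in 24 of 56 and fell in 8 in the PUB25 line (median 0.49) and rose in 30 of 60 and fell in 5 in the SPT line (median 1.63) in the authors' deposited table. WRKY factor genes rose in 9 and fell in 13 of 36 in the PUB25 line (median -0.24), and rose in 21 and fell in 3 of 40 in the SPT line (median 1.38), in the authors' deposited table. Kinesin genes fell in 17 of 31 and rose in 3 in the SPT line (median -1.43), and fell in 9 and rose in 6 of 31 in the PUB25 line (median -0.28), in the authors' deposited table. The signs of these medians held under quantile normalization and median centring.

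Several hormone and cell identity genes were called in opposite directions in the PUB25 and SPT lines in the authors' deposited table, chosen here after their values were seen. The auxin synthesis genes YUC8 and YUC9 fell from 106 to 28.6 and from 178 to 74.3 FPKM between Proximal and Distal in the PUB25 line and rose from 33.7 to 56.9 and from 70.3 to 187 FPKM in the SPT line. CEL5, a root cap cellulase gene, fell from 201 to 78.8 FPKM and rose from 43.4 to 313 FPKM in the same lines, and IAA30 fell from 91.5 to 18.16 FPKM and rose from 12.7 to 27.0 FPKM. The movement was the other way for SHR, at 2.58 and 21.5 FPKM in the PUB25 line and 16.7 and 6.73 FPKM in the SPT line, and for the hair patterning genes GL2 and GL3. GL2 stood at 4.72 and 20.8 FPKM in the PUB25 line and 7.36 and 2.58 FPKM in the SPT line. Jacalin lectin genes were among the most abundant in Distal cells, AT1G52060 (a name given to 2 assembled loci in the authors' zone files, of which the authors' deposited table carries 1) at 16464 FPKM in the PUB25 line, 14639 FPKM in the SPT line and 94.9 FPKM in the TMO5 line.

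In the TMO5 line genes at least 2-fold higher in Distal than in Medial cells outnumbered those lower. The authors' scaling is argued against as the whole cause, since 86.2% of such genes were still higher after quantile normalization. An even mix of cells of all other types at 5% or more of the Distal sort is argued against. A smaller even mix is not, nor are cells of 1 or a few other types. The 132 genes at 200 FPKM or more in SPT Distal and under 2% of that in TMO5 Medial stood higher in TMO5 Distal by a median of 1.04% of their SPT Distal level. The upper quartile was 2.85%, and 15 of these genes stood higher by 5% or more. How many of the rises an even mix of the size of that median could give was not computed. The 1312 genes picked as at least 2-fold higher in TMO5 Distal and at 5 FPKM or more in SPT Distal, where the authors' deposited table calls 326 risen in that step, stood higher by 18.02%, a value that their picking raises. A first comparison of marker lists, epidermis minus endodermis, did not decide (difference 1.18, standard error over members 0.67). In that step the epidermis list was higher (median 0.78, percentile 98.9) and the endodermis list lower (median -0.59, percentile 0.020). A response of the listed wounding and heat genes in the TMO5 Distal sort may contribute to the excess, as 14 of 14 were higher (median 1.46, percentile 100). Gene families by title were split. Heat shock genes were not higher (65 genes, median -0.02, percentile 85.1), but WRKY factor genes (27 genes, median 0.87, percentile 100) and glutathione S-transferase genes (53 genes, median 0.38, percentile 100) were. Families outside the stress response, such as aquaporin (18 genes, median 0.70, percentile 100), were higher as well. A biological difference between the zones stays open and untested.

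Vessel wall genes were lowest in Medial cells of the TMO5 line, with Proximal values a median of 38.1% of the way from Medial to Distal for the 16 genes at least 2-fold higher in Distal cells. A library of the Distal sort among those pooled as Proximal is argued against, since it would place other genes alike, and the 1051 other genes at least 2-fold higher in Distal cells, in rows of a single gene and at 5 FPKM or more in Distal, lay at 18.6% (vessel genes at percentile 99.9 among random sets of them). Whether 1 kind of maturing vessel cell in both the Proximal and Distal sorts could account for it cannot be told apart from other sources, because the SD of the Distal over Proximal log2 ratio over these genes, 0.57, lay at percentile 48.1 of random sets. The wounding and heat list dipped in Medial cells too (medians -0.41 and 1.46 in the 2 steps), so the dip was not special to vessel genes. A biological difference between the zones stays open and untested.

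Values outside the comparisons were as follows. AT2G01021, a locus of 102 bases on chromosome 2 (6571 to 6672) annotated as protein coding beside ribosomal RNA genes, carried between 748430 and 1733030 FPKM in the 9 populations. An unnamed locus of 58 bases on chromosome 5 (24741446 to 24741503) carried between 33963 and 78842 FPKM. Another unnamed locus, of 29551 bases on the mitochondrial genome, is listed at 0 FPKM in PUB25 Distal and between 7062 and 12874 FPKM in the other 8 populations. An unnamed locus of 73 bases on chromosome 5 (6324615 to 6324687) is listed at 0 FPKM in all SPT zones and between 2129 and 5366 FPKM elsewhere. The cause was not tested, so a listed 0 FPKM is not read as absence of RNA. In the PUB25, SPT and TMO5 lines 53, 98 and 63 rows were listed at 0 FPKM in 1 zone and at 20 FPKM or more in another, of which 10, 36 and 23 are protein coding in the reference.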
